A study of Mus musculus with 12 samples.

How the data were processed

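RNA sequencing libraries from 12 cultures of C57BL/6 mouse mammary epithelial cells were analysed. The cells had been grown for 48 h or 96 h either as monolayers on dishes coated with collagen or as spheroids inside Matrigel, a gel of basement membrane proteins from a mouse tumour. Each of the 4 combinations of culture format and time holds 3 libraries, which the series describes as biological replicates. Whether the replicates come from different animals is not given in the sources used here. Per the labels, total RNA was extracted, and mRNA libraries were made with Illumina TruSeq. The medium held progesterone and prolactin and was renewed in the gels after 48 h.

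The authors made the gene tables with bcl2fastq 2.15.0, Bowtie 1.0.1 and RSEM 1.2.30 on the mouse genome build mm9, with UCSC known genes as gene models. The strand setting and the program options are not given in the sources used here. The authors deposited expected counts, that is, the estimated reads per gene from RSEM, rounded to whole numbers. The unit follows from the tool named in the labels and from the values: 338 of them are a count of 0 beside an FPKM (fragments per kilobase of gene, scaled to library size) above 0, as rounding gives. The authors also deposited log2 values of FPKM plus 1, and a table that pairs each row with its mm9 gene symbols. Symbols were brought up to date with RefSeq names for GRCm38, another build than that of the counts, so no coordinates are given. Of the 28427 rows, 2093 carry more than 1 symbol. A symbol with more than 1 row was represented by the row with the larger mean count.

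Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 4 groups with a minimum count of 10 and a minimum total of 15, which left 13951 genes. Libraries were scaled by TMM, with factors from 0.923 to 1.07. A single quasi-likelihood model without intercept was fitted to all 12 libraries with group as its only term, and its common dispersion was 0.00501. There were 5 contrasts: spheroid against monolayer at 48 h, the same at 96 h, 96 h against 48 h in monolayers, the same in spheroids, and the culture format by time interaction, which is the spheroid effect at 96 h minus that at 48 h. Tests were 2-sided, with Benjamini-Hochberg adjustment in each contrast and a threshold of 0.05. The standard error (SE) of a log2 fold change was computed as its size divided by the square root of the quasi-likelihood F. An SE taken from the test this way can be too small where a group holds few counts. Levels are CPM values computed with TMM-adjusted library sizes. The terms rose, fell and changed are kept for what passed this threshold.

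A fold change against a group with a count of 0 is given as a bound, computed against a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio is given with its 95% counting interval, from the exact (Clopper-Pearson) interval of the binomial share of the pooled counts. Reads carried no molecular identifiers, so intervals and floors cover counting error only. Library totals lay between 7674105 and 13554497 counts, and 3 counts in a library stood for 0.221 to 0.391 CPM.

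The 27 gene lists, the contrasts, the alternatives and the rule for named genes were fixed before the data were examined. The lists cover chromosome segregation (spindle checkpoint and kinetochore; mitotic spindle and cytokinesis; cohesin, condensin and sister separation), DNA replication, p53 targets, integrins, focal adhesion and actomyosin, YAP/TAZ targets, epithelial junctions and polarity, milk and alveolar differentiation, luminal markers, basal and myoepithelial markers, mesenchymal transition genes, keratinization genes, basement membrane components, matrix proteases and inhibitors, hypoxia and glycolysis, cholesterol biosynthesis, unfolded protein and amino acid stress, interferon response, inflammatory and NF-kB targets, immediate early and heat shock genes, and housekeeping controls. Markers of fibroblasts, endothelial cells, immune cells and adipocytes stand for other cells that a mammary culture could hold. Of the 652 symbols on the lists, 651 had a row, and Hmgcs1 had none. The row for Knl1 was found under its older symbol Casc5. An alias first noted for Knl1 belongs to another gene and was dropped after the tables were opened. Rows such as those for Plk1 and Icam1 each merge several gene symbols, and in families of similar sequence, such as kallikreins, caseins and glutathione transferases, RSEM may have split reads between members. Each list was tested in each contrast with camera from limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 135 tests. The segregation lists were also tested with fry. List medians are log2 fold changes over the tested members, and counts of members are over the tested ones too. The adipocyte, keratinization and milk lists, among others, held further members that did not pass the filter on low counts.

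In each contrast the named genes were the 6 with the largest rise and the 6 with the largest fall among genes past the threshold with a mean log2 CPM of at least 3 and with groups that did not overlap (this last condition was dropped for the interaction), the called member of each list with the largest rise and with the largest fall, the member with the smallest p where a list had no called member, and 15 genes fixed by name. Of the list members chosen this way, only part are named in the text, and one is not reported here because it is withheld for evaluation. Genes outside this rule are said to be so where they appear.

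The alternatives were DESeq2-type size factors, upper-quartile scaling, scaling by total count alone, no filter beyond a count above 0, a stricter filter (at least 1 CPM in 3 libraries and 200 counts in all), DESeq2 1.42.0, limma voom, limma on the log2 FPKM values, a model of only the groups compared, the replicate number as a block, glmTreat against a change of 1.5-fold, and leaving out each library in turn. For every contrast the libraries were also split into other groups of the same sizes. The method was tested on simulated data in which 200 genes, 50 at each fold, were changed. Of genes changed 1.5-fold, 72%, 74%, 68% and 66% were called in the 4 contrasts between groups and 46% in the interaction. At 4-fold the shares were 96%, 98%, 96%, 94% and 90%. Of the calls in the simulated data, 4.79% were false for format at 48 h. In the other contrasts 5.99% to 8.38% were false, above the share that the threshold allows. The real contrasts called 39.8% to 73.8% of genes, far more than were changed in the simulated data. Change on that scale was not simulated, so the recovered and false shares cannot be carried over to the real contrasts. The limit set for the share recovered at 4-fold had been over 90%; it was lowered to 85% after the interaction gave 90%. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. No library was left out, and no data beyond these tables were used.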

Results

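The transcriptomes of mammary epithelial cells from C57BL/6 mice were measured in 12 RNA sequencing libraries. Monolayers were grown on dishes coated with collagen, and spheroids were grown inside Matrigel, a gel of basement membrane proteins. Each format was sampled after 48 h and 96 h, with 3 libraries in each of the 4 groups. Culture format and matrix, collagen or Matrigel, changed together, so their parts in any difference cannot be told apart. The cells in each format received progesterone and prolactin, hormones that act on milk-producing cells. The series concerns the control of chromosome segregation by what lies outside the cell, so the comparisons ask how culture format and time relate to the expression of segregation genes and of their surroundings. Library totals were 10723387, 12871930 and 12115074 counts in monolayers and 10459646, 8570530 and 8868804 counts in spheroids at 48 h. At 96 h they were 11641932, 7674105 and 10810094 counts in monolayers and 13025644, 12146881 and 13554497 counts in spheroids. After removal of genes with low counts, 13951 genes were tested.

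The first principal component held 59.6% of the variance and separated all monolayers from all spheroids. The second held 18.5%. Replicates of one group differed by more than counting error, with chi-square values per degree of freedom from 2.49 to 18.4, and the spread between replicates entered every test. The single most abundant gene took at most 2.36% of the counts of a library.

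**Figure D1:**
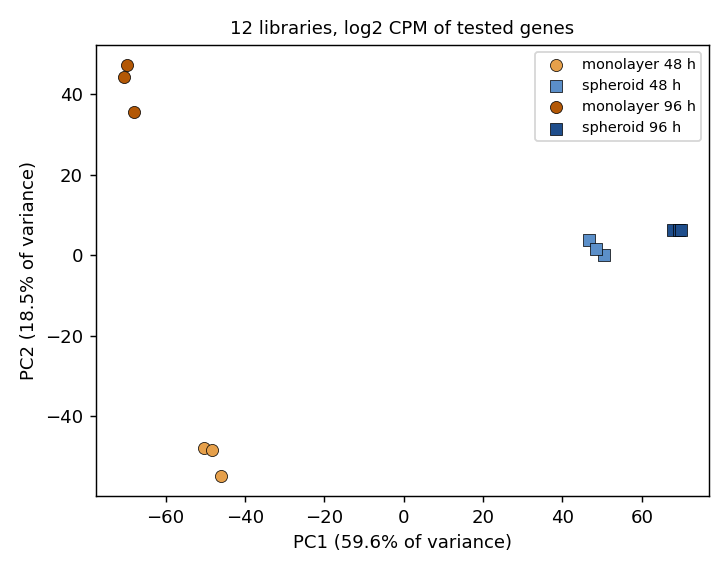
Each point is a library, placed by its first principal component (59.6% of variance) and second (18.5% of variance) of the log2 CPM values of tested genes, with 3 libraries in each of the 4 groups. Monolayers lay between -70.57 and -45.96 on the first component and spheroids between 46.78 and 69.78.

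The first comparison asked how cells in spheroids differed from cells in monolayers at 48 h. Milk genes were far higher in spheroids: Csn2, the gene of the milk protein beta-casein, stood at 76.3 ± 5.24 CPM against 0.582 ± 0.261 CPM (SD, n = 3 each), a 131-fold difference. Genes of adhesion and of the YAP/TAZ response, which reports mechanical tension, were lower: Ccn2, a standard YAP/TAZ target, fell from 3489 ± 286 CPM in monolayers to 118 ± 6.08 CPM in spheroids (29.5-fold lower), and Itgb1, the beta 1 integrin subunit, was 2.84-fold lower. Genes of the spindle checkpoint, which holds anaphase until chromosomes are attached, were modestly higher, with Bub1b 1.79-fold, Mad2l1 1.80-fold and Cdc20, the activator that the checkpoint restrains, 2.19-fold higher.

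Of the 13951 genes, 8081 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4402 higher and 3679 lower in spheroids, with 1330 higher and 1169 lower by over 2-fold. The log2 change was 7.04 ± 0.2 (SE) for Csn2 (adjusted p = 1.83e-15), -4.88 ± 0.111 for Ccn2 (adjusted p = 6.97e-17), 0.84 ± 0.106 for Bub1b (adjusted p = 1.62e-06) and 0.85 ± 0.0707 for Mad2l1 (adjusted p = 7.28e-09). Csn2 held 19 counts over the monolayers, so its SE, taken from the test, understates its error. Groups did not overlap for 60% of the tested genes, where chance gives 10%. Of 100 genes examined by name, 89 passed here, and the groups of all 89 did not overlap, a property the rule for naming asks of many of them.

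In the spindle checkpoint and kinetochore list, 31 of 37 measured genes rose and 1 fell (32 up and 1 down adjusted over the list alone; median log2 change 0.69, adjusted p = 1.07e-05 by camera). Spc24, part of the outer kinetochore, rose 2.60-fold, and Cenpc1, a protein of the inner kinetochore, was the member that fell (log2 change -0.36, or -0.21 on the log2 FPKM values). The mitotic spindle and cytokinesis list had 31 genes up and 2 down of 35 (median log2 change 0.61, adjusted p = 1.99e-05), with Ccna2, a mitotic cyclin, 2.51-fold higher and Numa1, a spindle pole protein, lower (-0.42). The proliferation marker Mki67 was 2.47-fold higher and Aurkb, a kinase that corrects chromosome attachment, 2.10-fold higher. A larger share of cycling cells in spheroids cannot be told apart here from higher levels per dividing cell. Of the cohesin, condensin and sister separation genes, 16 rose and 1 fell of 25 (median log2 change 0.41, adjusted p = 0.00158). DNA replication genes rose for 36 of 38 with none lower (median log2 change 0.97, adjusted p = 7.52e-12), among them Ccne2, a cyclin of S phase entry (3.40-fold). Tested with fry, the segregation lists rose with p from 2.58e-08 to 2.03e-05. With an estimated correlation the kinetochore and replication calls held (adjusted p = 0.0351 and 0.0242), while those of the mitotic spindle (adjusted p = 0.303 with an estimated correlation) and cohesin lists (0.225) did not.

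Of the 20 tested milk and alveolar genes, 19 rose and 1, Lcn2, fell (median log2 change 3.78, adjusted p = 3.49e-34). The median is 3.78 also with undetected members at their bound. Csn1s2a, another casein, had 524 counts in spheroids against 1 in monolayers, a ratio of 622 with a 95% counting interval of 111 to 24600. Elf5, a transcription factor of alveolar cells, was 23.0-fold higher. Luminal epithelial markers had 14 genes up and 5 down of 21 (median log2 change 1.00, adjusted p = 1.03e-08), with Ly6d 37.4-fold higher, yet Krt8, a luminal keratin, was 1.98-fold lower. Krt14, a basal keratin, was 2.09-fold higher, while the basal list as a whole did not pass. Keratinization genes, which build cornified epithelium, rose for 9 of the 12 tested (median log2 change 2.53, adjusted p = 2.56e-09). Spink5, a protease inhibitor of skin, had a ratio of 603 (95% counting interval 206 to 2930). All 6 tested adipocyte markers rose (median log2 change 2.58, adjusted p = 4.96e-07), including Fabp4 (8.24-fold). The other listed adipocyte markers and keratinization genes were too low to test. Elf5 and Fabp4 fall outside the naming rule in this comparison and were chosen after their values were seen.

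Focal adhesion and actomyosin genes fell for 29 of 31 (median log2 change -1.13, adjusted p = 8.5e-22), led by Tagln, an actin-binding protein (56.2-fold lower). YAP/TAZ targets fell for 21 of 24 (median log2 change -1.28, adjusted p = 4.23e-21), including Ankrd1 (32.4-fold lower). Among integrins 13 fell and 3 rose of 21 (median log2 change -0.62, adjusted p = 0.0296). Itga11, a collagen receptor subunit, was 12.8-fold lower, and Itga6, a subunit of laminin receptors, was 3.68-fold higher. Mesenchymal transition genes fell for 12 of 17 (median log2 change -0.75, adjusted p = 8.18e-05), with Vim 2.79-fold and Fn1, which encodes fibronectin, 8.86-fold lower. Cdh1, the E-cadherin gene, was 1.64-fold lower. The integrin call ended with an estimated correlation (adjusted p = 0.202) and without replicate 2 of the 48 h spheroids (adjusted p = 0.0571), within a range of 0.0014 to 0.202 over 19 alternatives. The mesenchymal call ended with an estimated correlation as well (adjusted p = 0.0592).

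Cholesterol biosynthesis genes fell for 20 of 24 (median log2 change -0.93, adjusted p = 9.98e-10). Interferon response genes fell for 21 of 25 (median log2 change -1.65, adjusted p = 4.07e-06), with Ifi44 17.3-fold lower. Hypoxia and glycolysis genes fell for 21 of 26 (median log2 change -0.44, adjusted p = 0.000111), with the angiogenic factor Vegfa 4.29-fold lower. Unfolded protein genes fell for 15 of 21 (median log2 change -0.57, adjusted p = 3.39e-06), basement membrane genes for 15 of 26 (median log2 change -0.49, adjusted p = 0.00317) and fibroblast markers for 9 of 15 (median log2 change -0.87, adjusted p = 0.00262). Matrix proteases and inhibitors fell for 11 of 22 (median log2 change -0.36, adjusted p = 5.09e-05), with the gelatinase gene Mmp9 23.3-fold lower. Of these lists the proteases kept their call with an estimated correlation (adjusted p = 0.0121). The others did not (cholesterol 0.125, interferon 0.255, hypoxia 0.125, unfolded protein 0.207, basement membrane 0.425 and fibroblast 0.248 as adjusted p with an estimated correlation). Apart from the integrins, the adjusted p of all lists that lost their call this way stayed at or under 0.0105 under the 18 other alternatives.

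The lists that did not pass were p53 targets (0.514), epithelial junctions (0.211), basal markers (0.326), NF-kB targets (0.421), immediate early genes (0.879), endothelial markers (0.707), immune markers (0.995) and housekeeping controls (0.678, all adjusted p). In the p53 target, NF-kB and immune lists the median and the mean differed in sign. Trp53, the p53 gene itself, did not pass (log2 change 0.03, adjusted p = 0.703), while its target Cdkn1a, an inhibitor of the cell cycle, was 1.48-fold lower. Adjusted over the list alone, the counts of 21 of the 27 lists were the same, and the largest difference was 2 members.

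Among genes with a mean log2 CPM of at least 3 and groups that did not overlap, the largest rises outside the lists were in Klk14, a secreted kallikrein protease (at least 274-fold, 693 counts against 0), Foxi1, a transcription factor of acid-secreting cells (1600 counts against 1, ratio 1900, 95% counting interval 340 to 75000), Aldh3a1, an aldehyde dehydrogenase (830-fold), and Atp6v1b1, a proton pump subunit (308-fold). The largest falls among them included Lce1h (205-fold, with 4 counts left in spheroids), P2rx2, an ATP-gated channel (93.0-fold), Dgkk (61.1-fold) and Ctsw (44.9-fold). The split into rises and falls depended on the scaling: 54.5% of called genes were higher here, against 65.1% with scaling by total count alone, which moved the median of all genes by 0.109 log2 units, and 65.2% on the log2 FPKM values (0.0658). The log2 FPKM values also gave changes smaller by over 1.5 times for genes near 0 in one group, such as Klk14 (5.15 on the log2 scale), Foxi1 (4.63), Csn1s2a (4.42) and Dgkk (-2.79).

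At 96 h the median rise of each list of chromosome segregation genes in spheroids was larger than at 48 h. Ccnb2, a mitotic cyclin, stood at 86.1 ± 2.63 CPM in spheroids against 1.46 ± 0.706 CPM in monolayers (SD, n = 3 each), 59.0-fold higher. Bub1b was 14.5-fold higher, Mad2l1 8.72-fold, Aurkb 20.1-fold, Cdc20 29.3-fold and Mki67 26.2-fold. Csn2 reached 964 ± 137 CPM in spheroids against 0.532 ± 0.246 CPM in monolayers, 1670-fold higher. Fn1 fell from 17520 ± 1700 CPM in monolayers to 499 ± 33.0 CPM in spheroids, 35.1-fold lower.

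The edgeR test called 10296 of 13951 genes, 5210 higher and 5086 lower in spheroids, with 1773 higher and 2380 lower by over 2-fold. The log2 change was 5.88 ± 0.158 (SE) for Ccnb2, 4.87 ± 0.145 for Cdc20 (adjusted p = 1.86e-15), 3.86 ± 0.134 for Bub1b (adjusted p = 1.29e-14) and 10.71 ± 0.180 for Csn2 (adjusted p = 2.67e-18). Monolayers held 18 counts of Csn2 and 46 of Ccnb2, so the SEs of these genes, taken from the test, understate their error. Groups did not overlap for 78.9% of tested genes, where chance gives 10%, nor for any of the 95 named genes that passed.

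All but 1 of the 37 spindle checkpoint and kinetochore genes rose (36 up and 0 down; median log2 change 2.98, adjusted p = 3.05e-35), with Cenpf, a kinetochore protein made before mitosis, 33.2-fold higher. Of the 35 mitotic spindle and cytokinesis genes 34 rose (median log2 change 3.86, adjusted p = 4.6e-65), including Nusap1 (59.0-fold) and Ccnb1 (43.9-fold). Cohesin and condensin genes had 19 up and 2 down of 25 (median log2 change 1.12, adjusted p = 6.64e-13), with the condensin subunit Ncapg 16.2-fold higher. DNA replication genes had 37 up and 1 down of 38 (median log2 change 2.10, adjusted p = 3.04e-27); Tk1, a nucleotide salvage enzyme, was 11.4-fold higher, and E2f1 was the member that fell (log2 change -0.50, or -0.86 on the log2 FPKM values). All these calls held with an estimated correlation (adjusted p from 0.00534 to 0.0245), and fry gave p of at most 6e-10 for the segregation lists. Among p53 targets 20 fell and 5 rose of 28 (median log2 change -0.74, adjusted p = 8.37e-05, lost with an estimated correlation, adjusted p = 0.176). Trp53inp1 was 5.78-fold and Cdkn1a 2.44-fold lower, and Trp53 was higher (log2 change 0.32). Ckap2, which is also on the mitotic spindle list, rose (1.75).

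Of the milk and alveolar genes 17 rose and 1 fell of 20 (median log2 change 4.22, adjusted p = 4.82e-27). Csn1s2a had 6486 counts in spheroids against 1 in monolayers, a ratio of 5330 (95% counting interval 957 to 211000), and Csn1s1 was 72.7-fold higher. Luminal markers rose for 18 of 21 (median log2 change 1.53, adjusted p = 1.22e-10), with Elf5 23.5-fold higher and Krt8 1.34-fold higher. Krt14 was 12.3-fold higher, while the basal list did not pass: its median was -0.95, its mean -0.04 and its test pointed up. Keratinization genes had 11 up and 1 down of 12 (median log2 change 2.28, adjusted p = 0.00115; median 2.16 with undetected members at their bound). Epithelial junction genes rose for 28 of 36 (median log2 change 0.73, adjusted p = 9.81e-05), including Tjp3, a tight junction scaffold (8.11-fold). Cdh1 was 1.11-fold higher (adjusted p = 0.0371), a call kept by 11 of 22 alternatives (adjusted p from 0.0177 to 0.405). It ended with DESeq2-type, upper-quartile and total-count scaling, the stricter filter and the log2 FPKM values, and without replicate 2 of the 48 h monolayers, replicate 1 or 2 of the 96 h monolayers or any 96 h spheroid.

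Mesenchymal transition genes fell for 14 of 17 with none higher (median log2 change -2.44, adjusted p = 1.54e-14). Integrins fell for 16 of 21 (median log2 change -1.28, adjusted p = 0.000154): Itgb3, a subunit of vitronectin receptors, was 8.94-fold, Itga5, a fibronectin receptor subunit, 8.32-fold and Itgb1 2.42-fold lower, while Itga8 (5.88-fold) and Itga6 (2.28-fold) were higher. YAP/TAZ targets fell for 17 of 24 (median log2 change -0.93, adjusted p = 5.58e-08), with Ccn2 13.7-fold lower. Matrix proteases and inhibitors fell for 18 of 22 (median log2 change -1.37, adjusted p = 1.99e-05), with Mmp9 42.2-fold lower and the inhibitor Timp3 higher (1.93). These calls held with an estimated correlation (adjusted p at most 0.0444). Focal adhesion genes fell for 20 of 31 (median log2 change -0.50, adjusted p = 0.000718), hypoxia genes for 16 of 26 (median log2 change -0.75, adjusted p = 9.56e-06), basement membrane genes for 17 of 26 (median log2 change -0.67, adjusted p = 0.0139), fibroblast markers for 9 of 15 (median log2 change -1.36, adjusted p = 0.000614) and endothelial markers for 13 of 14 (median log2 change -2.46, adjusted p = 0.000829). Cholesterol biosynthesis genes rose for 18 of 24 (median log2 change 0.84, adjusted p = 0.000555), with Idi1 5.15-fold higher. The calls in the preceding pair of sentences were lost with an estimated correlation (adjusted p = 0.248 for focal adhesion, 0.0819 for hypoxia, 0.502 for basement membrane, 0.189 for fibroblast, 0.111 for endothelial and 0.354 for cholesterol genes), but under the 18 other alternatives their adjusted p was at most 0.0272.

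Interferon response genes fell for 16 of 25 (median log2 change -0.69, adjusted p = 0.0281), a call lost with an estimated correlation (adjusted p = 0.572) and without replicate 3 of the 96 h monolayers (adjusted p = 0.0502), in a range of 0.00201 to 0.572. The lists that did not pass were basal markers (0.894), unfolded protein genes (0.353), NF-kB targets (0.171), immediate early genes (0.296), immune markers (0.263), adipocyte markers (0.471; median 1.15, or 0.71 at the bounds) and housekeeping controls (0.112, all adjusted p). NF-kB targets and housekeeping controls passed without the filter on low counts (adjusted p = 0.0282 and 0.0101, in ranges of 0.0282 to 0.502 and 0.0101 to 0.502). Within the NF-kB list, the chemokine gene Cxcl5 was 122-fold higher and Il6 41.1-fold lower. Adjusted over the list alone, 25 of 27 lists had the same counts, and the rest differed by 1 member.

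Among genes with a mean log2 CPM of at least 3 and groups that did not overlap, the largest rises besides Csn1s2a and Csn2 were in the kallikreins Klk10 (330-fold), Klk14 (ratio 345, 95% counting interval 61.5 to 13600) and Klk6 (ratio 220, interval 75.1 to 1070), and in Atp6v1b1 (271-fold). The largest falls among them were in the unnamed transcript AK220016 (at least 220-fold, 542 counts against 0), Lce1h (1 count against 103, ratio 125, interval 22 to 5000), Gvin1 (46.6-fold in the row with more counts), Dgkk (45.8-fold), Mmp9 and Star, a transporter of cholesterol for steroid synthesis (41.9-fold). AK220016 varied from 0 to 254 counts between replicates of 48 h groups, and with limma voom its adjusted p was 0.0551 (range over alternatives 7.4e-11 to 0.0551). On the log2 FPKM values the changes of genes near 0 in one group were smaller by over 1.5 times, for example -2.89 for Star, 3.04 for Cenpf and -2.98 for Il6 on the log2 scale.

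The spheroid effects at 48 h and 96 h share no libraries. In both, 2986 genes were called higher, against 1644 if the calls were independent, 2459 were called lower, against 1341, and 1059 were called in opposite directions, against 2979. Across the 13951 genes the log2 changes had a Pearson r of 0.583; genes are not independent replicates. Nusap1, Ccnb1, Csn1s1, Tjp3, Itga5 and Itgb3 fall outside the naming rule at 96 h and were chosen after their values were seen. Klk10, Atp6v1b1, Csn2, Elf5, Itga6, Itga8 and Krt14 were higher at both times, and Ccn2, Tagln, Itgb1, Vim, Fn1, Mmp9 and Cdkn1a were lower at both.

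**Figure D2:**
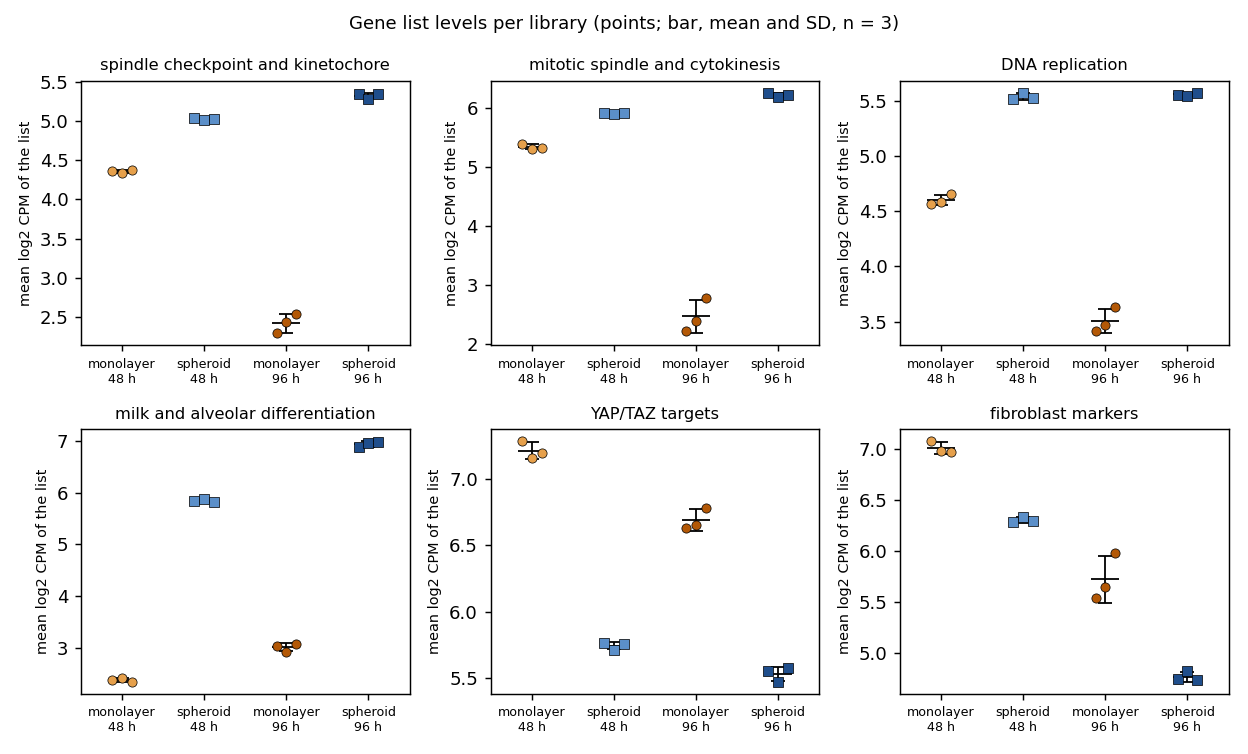
Each panel shows a gene list, with the mean log2 CPM of its members on the vertical axis for every library (points) in the 4 groups; bars give the mean and SD (n = 3). The mitotic spindle list is lowest in 96 h monolayers, where its median log2 change from 48 h is -3.09, and highest in 96 h spheroids.

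The third comparison followed monolayers from 48 h to 96 h. Genes of mitosis fell steeply: Ccnb1, the main mitotic cyclin, went from 68.6 ± 3.08 CPM to 3.29 ± 0.834 CPM (SD, n = 3 each), 20.7-fold lower, and Ccnb2 fell 24.8-fold. The checkpoint genes Bub1b and Mad2l1 fell 5.69-fold and 3.72-fold, Aurkb 7.95-fold, Cdc20 11.3-fold and Mki67 7.89-fold. Krt14 dropped 6.70-fold. Spp1, the secreted phosphoprotein osteopontin, rose from 344 ± 36.1 CPM to 5394 ± 130 CPM, 15.7-fold.

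The edgeR test called 8556 genes, 4196 higher and 4360 lower at 96 h, with 1193 higher and 1022 lower by over 2-fold. The log2 change was -4.37 ± 0.114 (SE) for Ccnb1 (adjusted p = 6.53e-15), -3.50 ± 0.158 for Cdc20 (adjusted p = 2.69e-12), -2.51 ± 0.147 for Bub1b (adjusted p = 8.67e-11) and 3.97 ± 0.0870 for Spp1. Ccnb1 held 105 counts over the 96 h monolayers, so its SE, taken from the test, may be too small. Groups did not overlap for 63.8% of tested genes, where chance gives 10%. They did not overlap for 82 of the 86 named genes that passed (Dgkk, Itga11, Fn1 and Gvin1 overlapped).

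In the spindle checkpoint and kinetochore list 34 of 37 genes fell (median log2 change -1.96, adjusted p = 1e-31), with Cenpa, the histone that marks centromeres, 16.3-fold lower. All 35 mitotic spindle and cytokinesis genes fell (median log2 change -3.09, adjusted p = 7.5e-83), including Nusap1 (23.6-fold), Aspm (20-fold) and Kif2c (19.7-fold). Cohesin and condensin genes fell for 15 of 25 (median log2 change -0.33, adjusted p = 1.34e-06; lost with an estimated correlation, adjusted p = 0.0687), with Top2a, which untangles chromosomes, 8.02-fold lower. The median of this list ranged from -0.37 to -0.157 over 19 alternatives. DNA replication genes fell for 32 of 38 (median log2 change -1.13, adjusted p = 1.11e-16), with Rrm1 4.62-fold lower and E2f1 higher (log2 change 0.45, or 0.84 on the log2 FPKM values). By fry the segregation lists fell with p of at most 1.27e-07. Among p53 targets 18 of 28 rose and 2 fell (median log2 change 0.51, adjusted p = 2.92e-06). That call was lost with an estimated correlation (adjusted p = 0.107). Trp53inp1 was 4.45-fold higher, and Ckap2, which is also on the mitotic spindle list, was lower (-0.79). Cdkn1a did not pass (log2 change 0.10 ± 0.0582, adjusted p = 0.135); it passed with upper-quartile scaling (0.16), total-count scaling (0.27) and the log2 FPKM values (0.27), in a range of adjusted p from 0.00024 to 0.337. Trp53 fell 1.33-fold, or by 0.24 log2 units with scaling by total count.

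Cholesterol biosynthesis genes fell for 23 of 24 (median log2 change -1.45, adjusted p = 1.06e-26), with Idi1 6.40-fold lower. Focal adhesion genes fell for 30 of 31 (median log2 change -0.84, adjusted p = 7.61e-15), with Tagln 8.99-fold lower. NF-kB targets fell for 17 of 24 (median log2 change -1.27, adjusted p = 1.1e-11), epithelial junction genes for 27 of 36 (median log2 change -0.55, adjusted p = 7.21e-07) with Cgn at -1.39 and Cdh1 1.54-fold lower, basal markers for 12 of 20 (median log2 change -0.84, adjusted p = 6.35e-07), luminal markers for 12 of 21 (median log2 change -0.42, adjusted p = 1.99e-05) with Aldh1a3 5.55-fold and Krt8 2.97-fold lower, and matrix proteases for 14 of 22 (median log2 change -0.31, adjusted p = 0.0059). These calls held with an estimated correlation (adjusted p at most 0.0444). YAP/TAZ targets fell for 15 of 24 (median log2 change -0.53, adjusted p = 8.84e-05), with Ccn2 2.39-fold lower. Basement membrane genes fell for 19 of 26 (median log2 change -0.61, adjusted p = 0.00113) and fibroblast markers for 11 of 15 (median log2 change -1.64, adjusted p = 2.39e-06), with Col3a1, a fibrillar collagen, 11.4-fold lower and Pdgfra 2.90-fold higher. Milk and alveolar genes rose for 12 of 20 (median log2 change 0.85, adjusted p = 0.00085; median 0.83 at the bounds): Csn1s1 rose 19.1-fold, from 0.240 ± 0.103 CPM to 4.76 ± 0.608 CPM, while Csn2 did not pass (-0.01 ± 0.525, adjusted p = 0.99). These last 4 lists lost their calls with an estimated correlation (adjusted p = 0.0708 for YAP/TAZ, 0.387 for basement membrane, 0.0513 for fibroblast and 0.0513 for milk genes). The other 18 alternatives gave lists with such a loss an adjusted p of at most 0.00504.

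The lists that did not pass were integrins (0.842), mesenchymal genes (0.378), keratinization genes (0.296; median -0.76, or -0.46 at the bounds), hypoxia genes (0.23), unfolded protein genes (0.255), interferon genes (0.109), immediate early genes (0.376), endothelial (0.471), immune (0.296) and adipocyte markers (0.995; median -0.23, mean and test upward) and housekeeping controls (0.0626, all adjusted p). Housekeeping controls had 14 genes down and 3 up of 21, with Ppia 2.12-fold lower. They passed without the filter (adjusted p = 0.00412), with a replicate block (0.0397) and without replicate 1 of the 48 h monolayers (0.0185), in a range of 0.00412 to 0.425. Interferon genes passed without the filter (adjusted p = 0.0451) and without replicate 2 of the 96 h monolayers (0.0198), in a range of 0.0198 to 0.663. Among integrins Itgb3 was 2.33-fold higher and Itgb6 4.12-fold lower, and Cd68, a macrophage marker, rose (3.34). Adjusted over the list alone, 22 of 27 lists had the same counts, with a largest difference of 2 members.

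Among genes with a mean log2 CPM of at least 3 and groups that did not overlap, the largest rises were in Atp6v0d2, a proton pump subunit (26-fold), Foxi1 (30 counts against 1, ratio 31.5, 95% counting interval 5.24 to 1290), Csn1s1, S100a8 (15.9-fold), Spp1 and Gsta4, a glutathione transferase (14.6-fold). Beside Ccnb2, Nusap1, Ccnb1, Aspm and Kif2c, Depdc1a had one of the largest falls at such levels (24.5-fold). The direction split again depended on scaling: 49% of called genes were higher here, 66.2% with scaling by total count, which moved the median of all genes by 0.171 log2 units, and 65.2% on the log2 FPKM values (0.122). The log2 FPKM values gave changes smaller by over 1.5 times for genes near 0 in one group, such as Foxi1 (0.51 on the log2 scale), Nusap1 (-3.01) and Aspm (-1.65).

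The last comparison between groups followed spheroids from 48 h to 96 h. Milk genes went on rising: Csn1s1 rose 65.7-fold, from 5.29 ± 0.454 CPM to 348 ± 51.3 CPM (SD, n = 3 each), and Csn2 12.6-fold. Checkpoint genes rose slightly, Bub1b 1.42-fold and Mad2l1 1.30-fold. Markers of fibroblasts, endothelial cells and adipocytes fell together, and so did mesenchymal genes, with Snai1, a transcription factor that represses E-cadherin, 7.17-fold lower.

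The edgeR test called 5547 genes, 2691 higher and 2856 lower at 96 h, with 335 higher and 1197 lower by over 2-fold. The log2 change was 6.04 ± 0.124 (SE) for Csn1s1 (adjusted p = 2.83e-16), 0.50 ± 0.0967 for Bub1b (adjusted p = 0.000414) and 0.38 ± 0.0661 for Mad2l1 (adjusted p = 0.00014). Groups did not overlap for 53.8% of tested genes, where chance gives 10%, and for 76 of 78 named genes that passed (AK220016 and S100a8 overlapped).

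Spindle checkpoint and kinetochore genes rose for 27 of 37 with none lower (28 up and 0 down adjusted over the list alone; median log2 change 0.31, adjusted p = 0.000172), including Spc25 (1.53-fold). Mitotic spindle genes rose for 22 of 35 (median log2 change 0.34, adjusted p = 1.88e-05), with Ccnb2 1.54-fold higher, and cohesin and condensin genes for 15 of 25 (median log2 change 0.30, adjusted p = 0.000172). All 3 calls were lost with an estimated correlation (adjusted p = 0.0592, 0.301 and 0.141), and fry gave p from 8.21e-06 to 0.00105. DNA replication genes did not pass (adjusted p = 0.597), with 5 up and 3 down of 38, or 0 up and 1 down adjusted over the list alone. Single genes of the cycle were near the threshold. Cdc20 was 1.19-fold higher (adjusted p = 0.0455) and passed under 10 of 22 alternatives (adjusted p from 0.0018 to 0.24), with its call lost under every other scaling and without any single spheroid library, among others. Mki67 was 1.34-fold higher (adjusted p = 0.0125) and missed the threshold with DESeq2 and without replicate 2 at 48 h or replicate 1 at 96 h (adjusted p from 8.76e-05 to 0.11). Tk1 (0.28, adjusted p = 0.0191) passed under 17 of 22 and missed on the log2 FPKM values and without replicate 1 or 3 at 48 h or 2 or 3 at 96 h (0.00286 to 0.0823). Cdkn1a was 1.53-fold lower, while Trp53 did not pass (adjusted p = 0.176).

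Milk and alveolar genes rose for 13 of 20 and fell for 4 (median log2 change 1.10, adjusted p = 8.3e-18), with Csn1s2a 8.97-fold and Lcn2, an iron-carrier protein, 2.50-fold higher. Epithelial junction genes rose for 19 of 36 (median log2 change 0.24, adjusted p = 0.000555), with Tjp3 2.54-fold and Cdh1 1.18-fold higher. Both calls held with an estimated correlation (adjusted p = 0.00255 and 0.0245). Interferon genes rose for 20 of 25 (median log2 change 1.08, adjusted p = 3.85e-07), with Ifi44 7.66-fold higher. Unfolded protein genes rose for 10 of 21 (median log2 change 0.22, adjusted p = 0.000148) and cholesterol genes for 13 of 24 (median log2 change 0.27, adjusted p = 0.0046). These last 3 calls were lost with an estimated correlation (adjusted p = 0.22, 0.277 and 0.467).

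All 15 fibroblast markers fell (median log2 change -1.43, adjusted p = 5.67e-19), with Pdgfra 4.91-fold and Col3a1 3.88-fold lower. All 14 endothelial markers (median log2 change -2.18, adjusted p = 1.65e-07) and all 6 tested adipocyte markers (median log2 change -1.97, adjusted p = 7.22e-12) fell, Fabp4 5.98-fold. Beside them, mesenchymal genes fell for 16 of 17 (median log2 change -1.69, adjusted p = 1.39e-29), integrins for 12 of 21 (median log2 change -0.63, adjusted p = 2.83e-05) with Itga5 4.03-fold and Itgb3 2.49-fold lower, and matrix proteases for 15 of 22 (median log2 change -0.78, adjusted p = 4.37e-09) with Mmp9 8.27-fold lower. Basal markers fell for 10 of 20 (median log2 change -0.53, adjusted p = 8.84e-05), keratinization genes for 9 of 12 (median log2 change -1.46, adjusted p = 9.8e-07) and NF-kB targets for 13 of 24 (median log2 change -0.38, adjusted p = 2.67e-06) with Il6 9.91-fold lower. These calls held with an estimated correlation (adjusted p at most 0.0415). Basement membrane genes fell for 16 of 26 (median log2 change -0.44, adjusted p = 6.71e-06), hypoxia genes for 15 of 26 (median log2 change -0.20, adjusted p = 2.75e-06) and immediate early genes for 12 of 23 (median log2 change -0.36, adjusted p = 0.00114), all lost with an estimated correlation (adjusted p = 0.231, 0.0642 and 0.116). Lists with such a loss had an adjusted p of at most 0.00837 under the 18 other alternatives. Pdgfra, Col3a1, Fabp4, Itgb3 and Lcn2 fall outside the naming rule in spheroids with time and were chosen after their values were seen.

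The lists that did not pass, besides DNA replication, were p53 targets (0.48), focal adhesion genes (0.0787), YAP/TAZ targets (0.367), luminal markers (0.0541), immune markers (0.417) and housekeeping controls (0.921, all adjusted p). Housekeeping controls had a median above 0 and a mean just under it. Luminal markers passed under 8 of 19 alternatives (adjusted p from 0.0287 to 0.304), and focal adhesion genes passed without the filter (adjusted p = 0.0296, range 0.0296 to 0.514). Itgb1, Krt14, Krt8 and Ccn2 did not pass (adjusted p = 0.065, 0.0613, 0.0857 and 0.246). They passed under 10, 8, 4 and 1 of 22 alternatives, with adjusted p from 0.00318 to 0.193, 0.00176 to 0.2, 0.00828 to 0.317 and 0.0347 to 0.54. Adjusted over the list alone, 15 of 27 lists had the same counts, and the largest difference, 7 members, was in DNA replication.

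Among genes with a mean log2 CPM of at least 3 and groups that did not overlap, the largest rises beside the caseins were in Gabrp, a subunit of GABA receptors (15.1-fold), Cbr2, a carbonyl reductase (12.9-fold), and Slc7a3, an amino acid transporter (11.3-fold). The largest falls among them were in Gsta1, a glutathione transferase (50.0-fold), Pdk4, a kinase that restrains glucose oxidation (11.2-fold), the chemokine Ccl2 (8.66-fold), Mmp9 (8.27-fold), the transporter Abcc4 (8.09-fold) and Adgra2 (7.84-fold). Changes with time in monolayers and in spheroids showed little relation: 847 genes were called higher in both, against 809 if independent, 950 lower in both, against 893, and 1905 in opposite directions, against 1700. The log2 changes had a Pearson r of -0.0365 across 13951 genes, which are not independent replicates. The log2 FPKM values gave changes smaller by over 1.5 times for genes of low level, such as Slc7a3 (2.21 on the log2 scale), Mmp9 (-1.83), Ifi44 (1.14) and Il6 (-1.23).

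**Figure D3:**
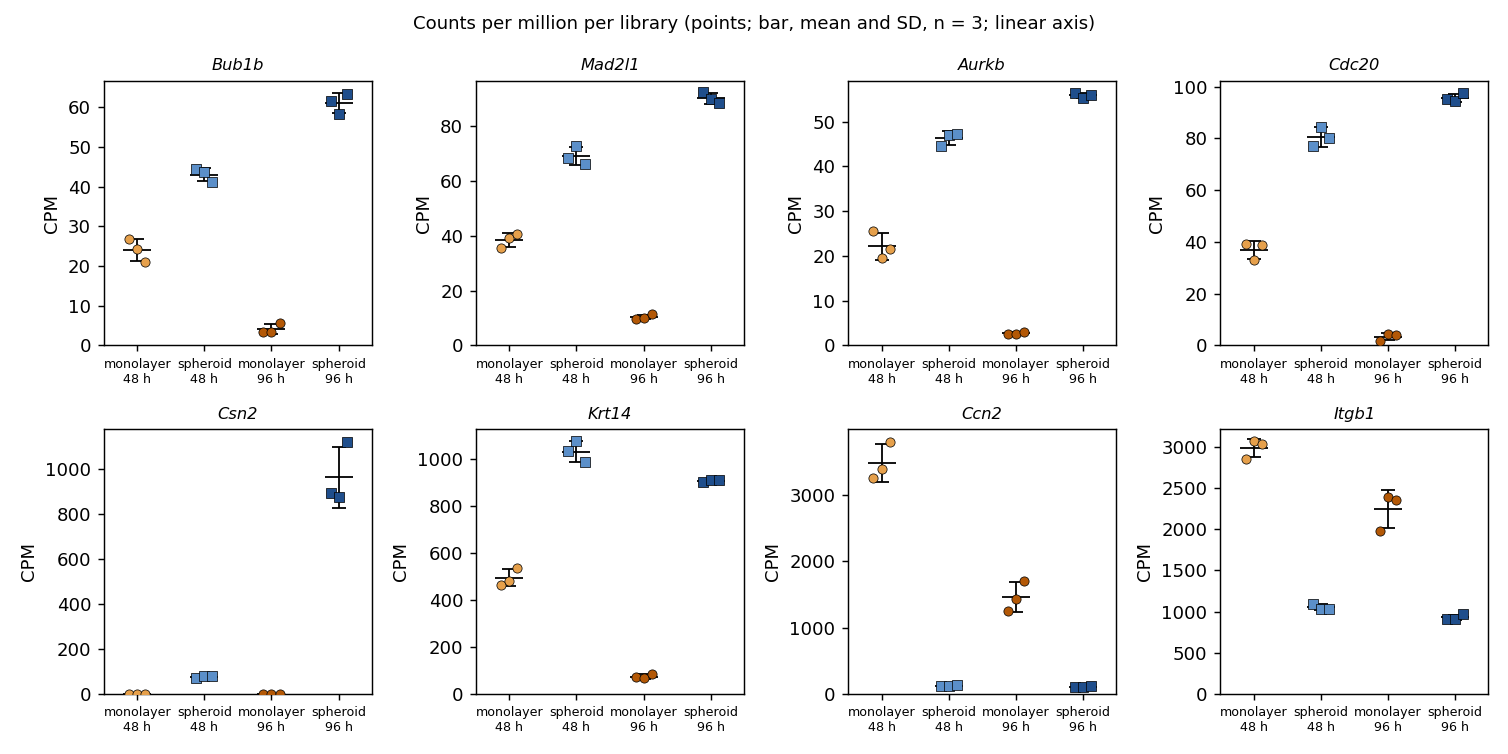
Levels of 8 genes in CPM (vertical axes, linear from 0) in every library (points) of the 4 groups; bars give the mean and SD (n = 3). Bub1b, for example, lies at 4.16 ± 1.29 CPM in 96 h monolayers and 61.0 ± 2.56 CPM in 96 h spheroids, and Csn2 at 0.532 ± 0.246 CPM and 964 ± 137 CPM.

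The interaction asked whether the spheroid effect differed between the times. For segregation genes it grew from 48 h to 96 h: by 3.01 ± 0.177 log2 units (SE) for Bub1b, an 8.06-fold change of the effect, by 2.28 for Mad2l1, 3.26 for Aurkb, 3.74 for Cdc20 and 3.41 for Mki67. Much of that growth lay in monolayers, where these genes fell with time by more than they rose in spheroids: Bub1b fell by 2.51 log2 units in monolayers and rose by 0.50 in spheroids. The medium was renewed in the gels after 48 h, and a part of this renewal in the values at 96 h cannot be told apart from format and time. The effect on Csn2 grew by 3.67 ± 0.588, where Csn2 rose by 3.66 in spheroids and its change in monolayers (-0.01 ± 0.525) did not pass. The fall of the YAP/TAZ target Ccn2 in spheroids became smaller by 1.11 log2 units. Krt8 turned from lower to higher in spheroids relative to monolayers (interaction 1.41). It fell by 1.57 log2 units with time in monolayers, while its change in spheroids (-0.16) did not pass. The effect on Cdh1 moved by 0.87.

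The edgeR test called 7433 genes, 3750 with an upward and 3683 with a downward change of the effect, with 1077 upward and 1859 downward by over 2-fold. The adjusted p was 1.23e-10 for Bub1b, 8.78e-12 for Mad2l1, 8.77e-12 for Aurkb and 4.38e-05 for Csn2. Trp53 passed (log2 change 0.28, adjusted p = 0.0271), but under only 12 of 21 alternatives, with adjusted p from 0.0131 to 0.51 and a value of 0.09 with scaling by total count; among single libraries, the call was lost without replicate 3 of the 48 h monolayers, replicate 1 of the 48 h spheroids, replicate 2 of the 96 h monolayers, or replicate 1 or 2 of the 96 h spheroids. Itgb1 and Vim did not pass (adjusted p = 0.074 and 0.564). They passed under 5 and 2 of 21 alternatives (adjusted p from 0.0306 to 0.705 and from 0.0339 to 0.975).

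All 35 mitotic spindle genes (median log2 change 3.35, adjusted p = 1.56e-86), 34 of 37 kinetochore genes (median log2 change 2.27, adjusted p = 2.54e-36), 17 of 25 cohesin and condensin genes (median log2 change 0.71, adjusted p = 7.99e-11) and 32 of 38 DNA replication genes (median log2 change 1.2, adjusted p = 3e-14) moved up. Cholesterol genes moved up for 22 of 24 (median log2 change 1.76, adjusted p = 8.03e-25) and junction genes for 29 of 36 (median log2 change 0.76, adjusted p = 1.08e-09). Mesenchymal genes moved down for 14 of 17 (median log2 change -1.69, adjusted p = 8.39e-10) and adipocyte markers for 4 of 6 (median log2 change -2.09, adjusted p = 0.00112). These calls held with an estimated correlation (adjusted p at most 0.0271), and by fry the segregation lists moved up with p of at most 4.21e-08. Focal adhesion genes (25 up and 1 down of 31; median log2 change 0.53, adjusted p = 3e-06), YAP/TAZ targets (13 and 5 of 24; median log2 change 0.35, adjusted p = 0.0139), luminal markers (10 and 6 of 21; median log2 change 0.17, adjusted p = 0.0135), unfolded protein genes (9 and 3 of 21; median log2 change 0.15, adjusted p = 0.000555) and NF-kB targets (14 and 5 of 24; median log2 change 0.62, adjusted p = 0.0275) moved up. The p53 targets (20 of 28 down; median log2 change -0.44, adjusted p = 2.55e-05), integrins (10 of 21 down; median log2 change -0.69, adjusted p = 0.00399) and endothelial markers (12 of 14 down; median log2 change -2.72, adjusted p = 5.52e-05) moved down. The calls in this pair of sentences were lost with an estimated correlation: adjusted p = 0.105 for focal adhesion, 0.239 for YAP/TAZ, 0.205 for luminal, 0.317 for unfolded protein, 0.24 for NF-kB, 0.139 for p53, 0.105 for integrin and 0.0708 for endothelial genes, against at most 0.0493 under the 18 other alternatives. The medians of the luminal and unfolded protein lists turned to -0.02 and -0.04 with scaling by total count, which kept their calls. The YAP/TAZ median ranged from 0.164 to 0.473 over 19 alternatives.

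Interferon genes moved up for 14 of 25 (median log2 change 0.71, adjusted p = 0.0353), a call lost with an estimated correlation (adjusted p = 0.572) and without replicate 2 of the 48 h spheroids (0.0528), replicate 2 of the 96 h monolayers (0.0621) or replicate 3 of the 96 h spheroids (0.0549), in a range of 0.00141 to 0.572. The lists that did not pass were milk genes (0.673), basal markers (0.363), keratinization genes (0.417), basement membrane genes (0.678), matrix proteases (0.123), hypoxia genes (0.0541), immediate early genes (0.211), fibroblast markers (0.218), immune markers (0.171) and housekeeping controls (0.124, all adjusted p). Milk, basement membrane and fibroblast lists had a median above 0 and a test that pointed down, with a mean below 0 for fibroblast markers only. Hypoxia genes passed under 8 of 19 alternatives (adjusted p from 0.0105 to 0.399), housekeeping controls under 2 (0.0119 to 0.502) and matrix proteases without replicate 1 of the 96 h monolayers (adjusted p = 0.0434, range 0.0434 to 0.189). Adjusted over the list alone, 18 of 27 lists had the same counts, with a largest difference of 2 members.

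Among genes with a mean log2 CPM of at least 3, the effect moved up most for Gabrp (6.00), the chemokine Ccl9 (5.86), Ccnb2 (5.25), Depdc1a (5.18), Nusap1 (5.18) and Slc7a3 (5.14), in log2 units. Of these, Slc7a3 went from 26.1-fold lower in spheroids at 48 h to 1.35-fold higher at 96 h. Ccl9 went from 2.49-fold lower to 23.3-fold higher. Among genes at such levels the effect moved down most for Gsta1 (-6.88), Gsta4 (-5.52), Star (-5.48), Abcc4 (-5.39) and Foxi1 (-5.18), and for AK220016, which missed the threshold with limma voom (adjusted p = 0.0731, range 9.01e-09 to 0.0731). Counts near 0 in one or more groups make the size of the Foxi1 and AK220016 values uncertain: on the log2 FPKM values Foxi1 moved by -1.13. Other values of this ranking were smaller there too, such as 3.78 for Gabrp, 3.60 for Ccl9, 2.87 for Depdc1a and -2.95 for Star. The direction split depended on scaling, with 50.5% of called genes upward here, 34.2% with scaling by total count, which moved the median of all genes by -0.188 log2 units, and 35.6% on the log2 FPKM values (-0.134).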

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

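The tests of a smaller share of cycling cells, of p53 activity, of RNA from Matrigel, of a fibroblast admixture and of a mixed admixture were chosen only after the result was seen. The flagged results are values for which a test of the difference, the culture format by time interaction, found that the spheroid effect at 96 h differed from that at 48 h. This held for 7433 genes, for 17 of 27 lists and for 84 of 100 genes examined by name. Values below for Atp6v1b1, Atp6v0a4, Rbp7, Cftr, Col6a3 and the fibroblast list, among others, have an interaction that did not pass. With an estimated correlation 9 of the 17 list calls ended, those of the focal adhesion, YAP/TAZ, luminal, unfolded protein, NF-kB, interferon, p53, integrin and endothelial lists. The interferon call ended also without replicate 2 of the 48 h spheroids (adjusted p = 0.0528), replicate 2 of the 96 h monolayers (0.0621) or replicate 3 of the 96 h spheroids (0.0549). Mdm2, Lama1, Atp6v1c2, Cftr, Atp6v0a4, Rbp7 and Car2 fall outside the naming rule and were chosen after values were seen. Library outliers were not sought, because each group has 3 libraries.

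By list median, the log2 difference of the effect was 2.27 for spindle checkpoint and kinetochore genes, 3.35 for mitotic spindle genes, 0.71 for cohesin and condensin genes and 1.2 for DNA replication genes. It was 1.76 for cholesterol biosynthesis, 0.76 for epithelial junctions, 0.71 for interferon response, 0.62 for NF-kB targets, 0.53 for focal adhesion, 0.35 for YAP/TAZ targets, 0.17 for luminal markers and 0.15 for unfolded protein genes, the last 2 of which turned to -0.0208 and -0.0373 with scaling by total count. It was -0.44 for p53 targets, -0.69 for integrins, -1.69 for mesenchymal genes, -2.09 for adipocyte markers and -2.72 for endothelial markers.

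Among genes of mitosis and replication the log2 differences were Bub1b 3.01, Mad2l1 2.28, Aurkb 3.26, Cdc20 3.74, Mki67 3.41, Ccnb2 5.25, Ccnb1 4.63, Ccna2 3.5, Cenpf 4.26, Cenpa 4.42, Spc24 1.34, Spc25 2.09 and Cenpc1 0.59. Others were Nusap1 5.18, Depdc1a 5.18, Aspm 4.74, Kif2c 4.78, Numa1 0.53, Ncapg 3.20, Top2a 3.30, Tk1 2.22, Rrm1 2.42 and E2f1 -0.67. For p53 and its targets they were Trp53 0.28, Cdkn1a -0.72, Pmaip1 -0.31, Trp53inp1 -2.57 and Ckap2 1.22. Epithelial and milk genes had Csn2 3.67, Csn1s1 1.78, Lcn2 0.51, Krt8 1.41, Krt14 2.56, Cdh1 0.87, Cgn 1.18, Cldn4 0.84, Tjp3 1.87 and Aldh1a3 2.003. Adhesion, cytoskeletal and matrix genes had Ccn2 1.11, Ankrd1 2.73, Tagln 1.76, Itga5 -1.96, Itga6 -0.69, Itgb3 -2.54, Itgb6 0.74, Fn1 -1.99, Mmp9 -0.86, Timp3 1.97, Snai1 -2.08, Col3a1 1.56, Postn 0.74 and Pdgfra -3.83. Inflammatory, vascular and immune genes had Cxcl5 4.02, Ccl9 5.86, Ccl2 0.93, Il6 -3.70, Ifi44 1.61, Vegfa -0.67, S100a8 -4.64, Spp1 -4.01, Cd68 -3.31 and B2m -0.31. Metabolic and transport genes had Idi1 2.82, Psat1 2.95, Slc7a3 5.14, Pdk4 -4.86, Fabp4 -3.52, Star -5.48, Tfrc 0.84, Ppia 1.32, Abcc4 -5.39, Gsta1 -6.88, Gsta4 -5.52, Aldh3a1 -3.63 and Cbr2 4.14. The remaining genes had Klk6 1.76, Foxi1 -5.18, Atp6v0d2 -3.92, Spink5 -4.03, P2rx2 1.49, Ctsw 2.002, Gabrp 6.00, Adgra2 -1.65 and AK220016 -11.09. For Foxi1, Klk6, Spink5 and AK220016 a group at or near 0 counts leaves the size of the difference uncertain.

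For the comparisons of 3 libraries with 3 others there are only 10 ways to split the libraries, so the share of splits with as many genes cannot go under 0.1. The real grouping called 8081 genes for format at 48 h, 10296 at 96 h, 8556 for time in monolayers and 5547 in spheroids, each the 1 split with as many, and the highest other split called 0, 0, 0 and 1. For the interaction 1 of 100 splits, the real one, called 7433 genes or more and the highest other called 1488. Those other splits mixed culture formats and times within groups, which widens the spread and lowers the calls. They therefore cannot exclude chance for the interaction itself.

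Chromosome segregation and spindle genes were lower at 96 h than at 48 h in monolayers. Scaling is argued against, since the mitotic spindle list had a median log2 change of -3.11, -3.03 and -2.92 under the 3 other scalings. A smaller share of cycling cells stays open as the whole cause: the replication list fell less than the mitotic list, by 1.96 log2 units, but cells that leave the cycle can keep replication transcripts. An effect of p53 activity stays open too, with Cdkn1a at 0.103 (upper 95% bound 0.217) against Mdm2, which rose by 1.41 ± 0.0891 (SE, adjusted p = 2.45e-10), and 18 of 28 targets higher, though the call of that list ended with an estimated correlation (adjusted p = 0.107) and Trp53 itself fell (-0.41). One hypothesis is that fewer cells divided in monolayers by 96 h, which these data cannot tell apart from lower transcript levels per dividing cell. The same limit holds for the higher levels of segregation genes in spheroids than in monolayers at 48 h and 96 h. A part of the medium, which was renewed in the gels after 48 h, was not tested, and no group separates this renewal from format and time.

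Foxi1 and the proton pump subunit Atp6v1b1 were higher in spheroids at both times, at 56.3 ± 6.90 CPM and 49.6 ± 2.02 CPM at 48 h (SD, n = 3). A general rise of the pump is argued against by its 13 broadly used subunits, with median log2 changes of -0.104 at 48 h and 0.0646 at 96 h. For RNA carried over from Matrigel, Lama1 was examined, a laminin chain abundant in the tumour that the gel is made from. It was lower in spheroids than in monolayers (-2.49 ± 0.215 at 48 h and -2.41 ± 0.252 at 96 h, SE). Monolayers thus held Lama1 of their own. A fall of the cells' own transcript could hide carried-over RNA, so Lama1 cannot decide this. An acid-secreting cell programme stays open: of 13 further genes listed for it 2 passed the filter on low counts, and 1 of them, Atp6v1c2, was higher at both times (2.22 and 4.16), while Cftr did not pass the test. The other 11 had rows with a mean of at most 0.773 CPM in any group and were not tested. Rhbg had 22 and 21 counts in spheroids at 48 h and 96 h, against 5 and 4 in monolayers. P2ry14 (4 and 4 against 17 and 14) and Kcnma1 (8 and 8 against 17 and 21) went the other way. The rest held at most 2 counts in any group. Such levels are too near the floor to count for the programme or to exclude it. Among the genes noticed first, Atp6v0a4 (7.08 at 48 h and 6.68 at 96 h) and Rbp7 (7.69 and 6.88) were higher at both times, whereas Atp6v0d2 was higher and then lower (2.49 and -1.43) and Car2 lower and then higher (-1.11 and 3.27). Such cells may have arisen in spheroids, which these few genes cannot settle.

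Fibroblast, endothelial and adipocyte markers were lower at 96 h than at 48 h in spheroids, Pdgfra going from 90.8 ± 5.8 CPM to 18.5 ± 1.02 CPM and Col3a1 from 419 ± 37.4 CPM to 108 ± 4.34 CPM (SD, n = 3). Scaling is argued against, since the fibroblast median stayed at or below -1.44 under the other scalings. Loss of a single mixed admixture of fixed makeup stays open: the 3 list medians fell by amounts that lay 0.746 log2 units apart, at -1.43 for fibroblast, -2.18 for endothelial and -1.97 for adipocyte markers, with interquartile ranges that overlap. Loss of fibroblasts alone could account for the fibroblast part: all 15 markers fell, with an interquartile range of 0.604 in their log2 changes. A change within epithelial cells stays open and untested, since the labels name no sort. The marker Col6a3 was 4.09-fold higher in spheroids at 48 h and Pdgfra rose 2.90-fold in monolayers, though no marker of these lists is on another list. The fibroblast list as a whole fell with time in monolayers too (median log2 change -1.64), with Col3a1 11.4-fold and Col6a3 3.98-fold lower. Its fall was thus not particular to spheroids, though the monolayer call ended with an estimated correlation.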

How the results depend on the processing

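No alternative reversed the direction of a called list or of a called named gene, and no test in this part was chosen after the result was seen. Among all genes called by both methods, limma on the log2 FPKM values gave the opposite direction for 2 at 48 h, 1 in spheroids with time and 3 in the interaction; the cause was not tested. With scaling by total count the interaction medians of 2 called lists changed sign, to -0.0208 for luminal markers and -0.0373 for unfolded protein genes, while their tests stayed upward and past the threshold. Of the recomputed counts of genes, 109 stayed within 1.5 times the reported count. The other 5 come from testing against a change of 1.5-fold, which by construction calls fewer genes: 2912 for format at 48 h, 5278 at 96 h, 2524 for time in monolayers, 1427 in spheroids and 2999 for the interaction. DESeq2 called 7606, 9944, 7951, 5072 and 6979 genes, limma voom 8042, 10337, 8586, 5543 and 7454, and limma on the log2 FPKM values 8197, 10148, 8684, 5051 and 7616. With a single library left out the counts ranged from 7417 to 8145, 9784 to 10687, 7610 to 8644, 4537 to 6179 and 6834 to 7724. The replicate numbers gave no sign of pairing, with 18 pairs of equal number correlated from -0.11 to 0.0881 after removal of group means, and a replicate block called 8110, 10287, 8537, 5501 and 7417. Of the list results 2491 kept their side of the threshold, 27 newly passed and 47 no longer passed, 42 of these with an estimated correlation. Of the named gene results 7656 kept their side, 33 newly passed and 76 no longer passed. Scaling by total count moved the median of all genes by 0.109 log2 units at 48 h, 0.171 for time in monolayers and -0.188 for the interaction, so the balance of rises and falls there rests on the scaling; the cause was not tested. Depth limits genes near 0: 3 counts in a library stood for 0.221 to 0.391 CPM. Some changes of such genes, as of Klk14 and Foxi1 at 48 h, were smaller on the log2 FPKM values (5.15 and 4.63). The 1 added to FPKM before the log2 shrinks a change against a group near 0 by arithmetic. Any further cause was not tested.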

Other observations

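The test of the kallikreins was chosen in its present form only after the result was seen; the antioxidant test was set before, but after Aldh3a1, Gsta1, Gsta3, Gsta4, Slc7a11, Abcc4 and Fth1 had been noticed. Nqo1, Gclc, Gstm1, Hmox1, Klk7, Klk8 and Klk1b1 fall outside the naming rule and were picked as examples after their values were seen. The 7 genes noticed first, such as Aldh3a1 and the glutathione transferase Gsta4, were noticed because they were higher in spheroids at 48 h, and detoxification genes were not tested as a class. A shared antioxidant response was tested on 14 genes other than these 7. All 14 were higher in spheroids than in monolayers at 48 h, with a median log2 change of 1.2, among them Nqo1, a quinone reductase (4.37 ± 0.0936, SE), Gclc, an enzyme of glutathione synthesis (2.52 ± 0.078), Gstm1 (2.25) and Hmox1, which breaks down heme (1.16). At 96 h 3 were higher and 6 lower, with a median of -0.146, and Hmox1 was lower (-2.97). With time 13 rose in monolayers (median 0.562, Hmox1 2.54) and 13 fell in spheroids (median -0.619). The 48 h values may reflect an antioxidant response early in Matrigel, a hypothesis found and tested on the same libraries.

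Kallikreins, a family of secreted serine proteases, were examined as a group because Klk14, Klk10 and Klk6 had been named for large rises. A shared rise of the gene family was tested on the 3 other members measured, and 2 of these, Klk8 and Klk1b1, passed as higher in spheroids at both 48 h and 96 h, too few members to decide. Klk8 was higher by 1.12 and 0.86 log2 units, and Klk7 by 3.72 at 48 h, while at 96 h it did not pass (0.37, adjusted p = 0.664; interaction -3.34, adjusted p = 0.00568). Klk1b1 had 0 CPM in monolayers, against 1.578 CPM in spheroids at 48 h and 4.986 CPM at 96 h. From 48 h to 96 h in spheroids Klk1b1 rose (1.64), while Klk8 and Klk7 fell (-0.89 and -3.52). The members share sequence, so reads split between them could add to a common rise, which was not tested.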
